A study of Mus musculus with 4 samples.

How the data were processed

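RNA sequencing of NIT-1 cells, a pancreatic β cell line derived from NOD/Lt mice, was analysed in 4 libraries, 2 from cells transfected with a control plasmid that carries EGFP and 2 from cells transfected with a plasmid that carries ERRγ, the oestrogen-related receptor encoded by Esrrg. Per the labels' protocols, cells of passages 20 to 25 received 8.3 µg of plasmid with 16 µL of a liposomal reagent, RNA was isolated with Trizol, and paired-end Illumina libraries were prepared, with 2 biological replicates per group. Groups and replicate numbers were taken from the sample titles. The submitters' processing notes name the genome build mm8; the aligner, the counting program and the annotation are not given in the sources used here.

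Each library has a table that gives, per the file headers, a gene ID, an RPKM value, a count of unique gene reads and a count of total gene reads. The RPKM values and both kinds of count were made by the authors and deposited side by side; whether a read stands for 1 mate or 1 fragment is not stated. The 4 tables list the same 409 rows in the same order. Of these, 406 rows carry a gene ID, with 373 distinct IDs that all matched a symbol, and 3 rows carry the ID 0. The 3 unnamed rows held between 0.0121% and 0.0332% of the listed reads of a library and stayed out of library sizes and tests. The rule by which the 409 rows were chosen is not stated. In 355 of the 406 named rows (87.4%) the values of the groups did not overlap, where chance gives 33.3% for 2 libraries against 2. The rows were therefore treated as chosen on these same samples, and no count below is independent evidence of a change.

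Dividing each row's total reads by its RPKM gives the row length times the size of the library. A single library size per table made the length of all 406 named rows whole, within 0.01 nucleotides, and the length of a row differed by at most 0.00028 nucleotides between libraries. Of the 406 lengths, 397 equalled that of exactly 1 annotated transcript of the row's own gene in GENCODE M21 on GRCm38, 2 equalled several and 7 equalled none. The rows were therefore read as transcripts, although the headers speak of genes, and are written with the transcript name where there was 1 match (Hspa1b-201). By annotation 267 rows were protein-coding transcripts, 44 had a retained intron, 31 were processed transcripts and 25 were subject to nonsense-mediated decay. A row described by the product of its gene need not be the coding transcript. The transcripts annotated as pseudogenes were aligned with blastn 2.17.0 to all protein-coding transcripts to find the closest protein-coding gene. No coordinates of mm8 were used; positions are from GENCODE M21 on GRCm38.

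The recovered library sizes were 18769899 and 16895471 reads for control replicates 1 and 2, and 16605943 and 17466192 reads for ERRγ replicates 1 and 2. The listed rows held 7.62%, 7.51%, 6.41% and 6.26% of these reads. Uniquely placed reads made up 42.4%, 43.0%, 42.1% and 41.8% of the listed reads. They were unevenly spread: 309 rows had under 10% unique reads, 68 rows had at least 50%, and the median over rows was 1.29%. For a transcript of 1 kb, 3 reads correspond to between 0.160 and 0.181 RPKM; such limits cover counting error only.

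The groups, the all-read test described next, 26 gene lists, the rule for named rows and the alternatives not said to be added were chosen before the data were examined. The all-read test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) of ERRγ against control on total read counts, with TMM factors on the tables' own column totals, filterByExpr, no replicate block, and a Benjamini-Hochberg adjusted p under 0.05. A column total of a selected list is not the depth of a library, and most rows share their reads with other transcripts, so further tests were chosen after seeing the data. The library-total test used the same counts with the recovered library sizes and no TMM. The unique-read test used the unique read counts with the recovered library sizes and tested 121 rows. Its fit had a common dispersion of 0.0138, against 0.532 in the all-read test. Its prior degrees of freedom, the weight given to the spread pooled over rows, were 31.6 against 2.44. Its small p-values from 2 against 2 libraries thus lean on spread pooled over rows that appear chosen on these same samples. The unique-read test was also run with TMM in place of the library sizes. Log2 fold changes are ERRγ over control, and their standard errors (SE) were derived from the fold change and the F statistic. The lone library of a group with the other left out was assumed to vary like the libraries of the other group. Going from library sizes to TMM moved the log2 fold changes by a median of 0.16 with all reads and 0.34 with unique reads. Adjusted p-values are from edgeR unless another tool is named. DESeq2 1.42.0 was run beside edgeR, and limma 3.58.1 on log2(RPKM + 1), for rows with a mean RPKM of at least 1, was added after seeing the data. Alternatives also were other normalizations, other filters, the rows of a gene added up, a replicate block, a minimum log2 fold change of 1 and leaving out each library in turn.

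On data simulated from the libraries, up to 200 rows were changed by known folds, about as many raised as lowered. At the fitted dispersion the all-read test recovered 19.1% of the tested rows changed 1.5-fold, 17.4% at 2-fold, 34.8% at 4-fold and 55.3% at 16-fold. It tested 376 rows and called 2 of 190 unchanged rows. The unique-read test recovered 80% at 1.5-fold, 86.7% at 2-fold, 93.8% at 4-fold and 100% at 16-fold among 125 rows tested, and called 0 of 57 unchanged rows. Its simulated depths were the recovered library sizes, so false calls from a wrong scaling could not appear.

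Of the 26 gene lists, the 7 with at least 5 tested rows were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Camera compares a list with the other listed rows only, and fry tests a list against no change. At an estimated correlation camera takes its degrees of freedom from the residuals of the 4 libraries, which leaves it little power. For the ribosomal list, with an estimated correlation of −0.0253, camera's unadjusted p went from 0.209 at the preset to 0.328. A miss at an estimated correlation is thus no evidence against a shared shift. A call at the preset rests in turn on the assumed 0.01. In the all-read settings the estimate was 0.918 for the NF-kB list and 0.284 for the interferon list. It was 0.157 for the immediate early list and 0.0914 for the heat shock list. The rule for named rows took Esrrg, Esrra and Esrrb, up to 12 rows per direction past the threshold with non-overlapping groups, or the 5 with the smallest p where none passed, up to 4 rows of each list by p, and the 4 rows with the highest mean RPKM. Of the rows this rule took, 2 are not reported here. Esrra and Esrrb, and the lists for β cell identity, cell cycle, α, δ and PP cell markers, acinar and duct markers and immune cell markers, had no listed row and were not analysed here. Libraries were compared by the Pearson correlation of log2(RPKM + 1) across rows. Figures were drawn with matplotlib 3.10.9.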

Results

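The series asked which genes change with ERRγ in pancreatic β cells. NIT-1 cells, a β cell line from NOD/Lt mice, were transfected with an EGFP control plasmid or with a plasmid for ERRγ, an orphan nuclear receptor known for driving mitochondrial genes. RNA was sequenced in 2 libraries per group, with 16605943 to 18769899 reads per library as recovered from the tables. Neither untransfected cells nor an empty plasmid were among them, so every difference below is between ERRγ and EGFP. The tables hold 406 named rows, nearly all of which match a single annotated transcript, for 267 of them a protein-coding one. Since these rows are a selection by an unstated rule that appears to have used these same libraries, no count or direction below is independent evidence.

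The transfected gene separated the groups. Esrrg lies on chromosome 1 from 187608791 to 188214885 on the plus strand (GRCm38). Its transcript Esrrg-201 stood at 0.232 and 0 RPKM in control replicates 1 and 2, from 23 and 0 reads, and at 141 and 78.6 RPKM in ERRγ replicates 1 and 2, from 12398 and 7262 reads. A further transcript, Esrrg-203, stood at 0 and 0.355 RPKM in the controls and at 8.42 and 40.7 RPKM in the ERRγ libraries, and none of its reads was uniquely placed. The log2 fold change of Esrrg-201 was 9.98 ± 1.05 (SE) in the all-read test and missed its threshold (edgeR, adjusted p = 0.0588). Esrrg-201 rose in the library-total test (9.82 ± 1.05, edgeR, adjusted p = 0.0342) and in the unique-read test (9.65 ± 0.50, edgeR, adjusted p = 5.73e-18). In the all-read test both Esrrg rows, the only listed rows of the ERR list, passed when adjusted over the list alone. Reads from the plasmid and from the chromosomal gene were not told apart.

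Across all rows, Hspa1b, an inducible HSP70 chaperone, was the 1 row of 373 that passed the all-read test, and it was lower. Unadjusted p was under 0.05 for 141 rows, and 57 rows had an adjusted p between 0.05 and 0.06. Hspa1b lost its call without control replicate 2, where 0 of 401 rows passed (169 at an unadjusted p under 0.05), and without ERRγ replicate 1 or 2 the test called 2 or 4 rows. The DESeq2 Wald test called 200 rows, 111 higher and 89 lower. Both following tests were chosen after seeing the data. The library-total test called 25 of 375 rows, 4 higher and 21 lower, and 1 or 2 rows with any single library left out. The unique-read test called 73 of 121 rows, 11 higher and 62 lower, and with TMM 41 of 120 rows, 29 higher and 12 lower, so the split between higher and lower depended on the scaling.

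A small core of the unique-read calls held whichever library was left out. These 10 rows were Esrrg-201, which rose, and 9 rows that fell: Hspa1b-201, Hspa1a-201 and Gm20481-201 of the HSP70 loci, the inflammatory genes Nos2, Cxcl1 and Csf2, the interferon-induced gene Ifit2, the matrix glycoprotein gene Thbs1, and the predicted gene Gm9817. All 10 also passed with TMM. Of them Gm20481, Csf2 and Gm9817 lie outside the rule for named rows and were chosen after their values were seen. Of the 73 calls, 52 held without control replicate 1, 68 without control replicate 2, 14 without ERRγ replicate 1 and 10 without ERRγ replicate 2. Every other unique-read call named below was lost without ERRγ replicate 2. With an ERRγ library left out, the spread was taken from the controls alone. These differed more from each other than the ERRγ libraries did (chi-square per degree of freedom 96.5 against 40.6). A call lost there thus cannot be read as dependence on that ERRγ library.

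The heat shock genes were lower in both ERRγ libraries. All 9 rows of the oxidative stress and heat shock list lay below both controls in RPKM, and their log2 fold changes were negative in each of 5 settings of scaling and test. Hspa1b, on chromosome 17 from 34956436 to 34959238 on the minus strand (GRCm38), fell from 147 ± 12.5 RPKM (SD, n = 2) to 6.29 ± 0.462 RPKM, a ratio of 23.4 (log2 fold change −4.38 ± 0.13, edgeR, adjusted p = 0.000613). Without control replicate 2 its adjusted p was 0.0514. Its near-identical neighbour Hspa1a (chromosome 17, 34969190 to 34972156, minus strand) had 17.2 ± 2.86 RPKM in control and 0.558 ± 0.244 RPKM in ERRγ (SD, n = 2). Reads shared by these genes can be assigned to either, so each value is uncertain on its own. Gm20481, annotated on the opposite strand inside the Hspa1a locus (34969912 to 34972136), had 49.8 ± 8.83 and 1.89 ± 0.656 RPKM, and since the counting is not stated to use strand its reads cannot be told apart from those of Hspa1a.

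Other members of the list differed less. Hsph1-201, for an HSP110 co-chaperone, had 53.1 ± 3.80 RPKM in control and 22.6 ± 0.461 RPKM in ERRγ (SD, n = 2), and Hspb1-201, for a small heat shock protein, had 711 ± 142 and 363 ± 8.88 RPKM. In the all-read test 1 of the 9 rows passed, and 7 passed when adjusted over the list alone. The library-total test called 6 rows lower. Of 5 rows with enough unique reads, the unique-read test called 4 lower, and 2 with TMM. Hspb1-201 lost its unique-read call without ERRγ replicate 1 or 2 (edgeR, adjusted p = 0.148 and 0.292). The list stood below the other rows in camera (adjusted p = 0.000567). With an estimated correlation, where camera has little power, it did not pass (adjusted p = 0.610). In fry with the settings of the all-read test its adjusted p was 0.0310, and 0.0691 to 0.778 for the other 6 lists. Of these the interferon and immediate early lists passed in fry with DESeq2 size factors (0.0296 and 0.0296), a mean count of at least 50 (0.0468 and 0.0367), library totals (0.0347 and 0.0325), unique reads with library totals (0.0406 and 0.0406) and added rows of a gene (0.0276 and 0.0276), and the interferon list without ERRγ replicate 2 (0.0294). Neither passed with column totals, without a filter, with the replicate block, with unique reads under TMM or with any other library left out. The fry call of the heat shock list was lost with column totals (0.0529), without a filter (0.0521), with the replicate block (0.223), and without control replicate 2 (0.113), ERRγ replicate 1 (0.232) or ERRγ replicate 2 (0.374).

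**Figure D1:**
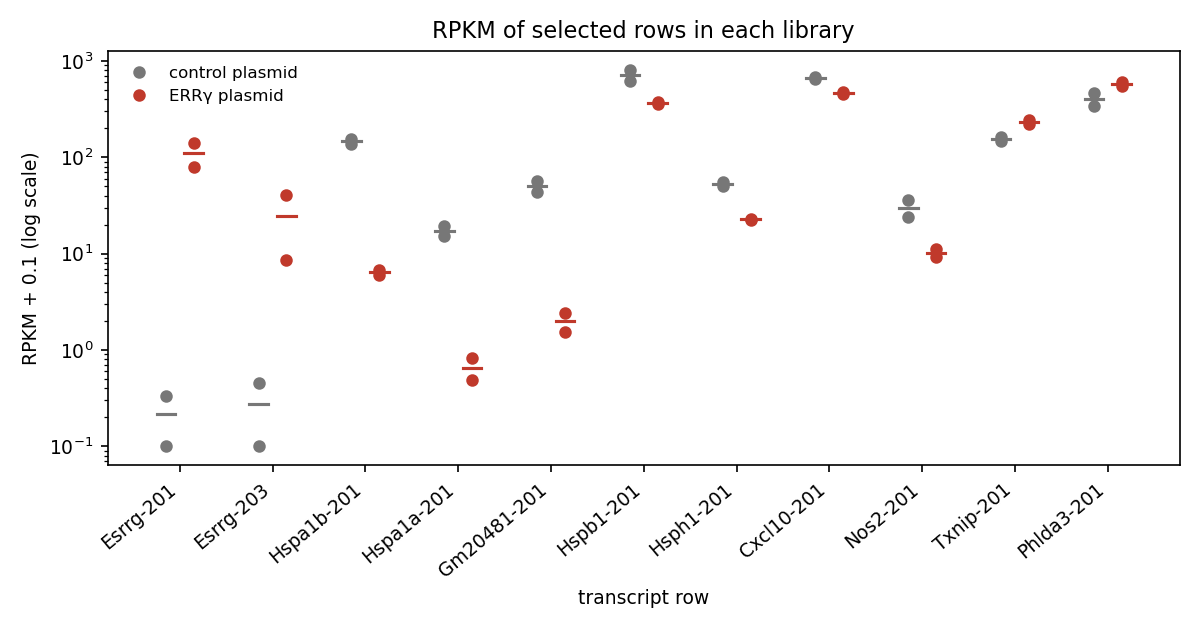
RPKM plus 0.1 on a log axis for 11 rows, with 1 point per library, grey for the control plasmid and red for the ERRγ plasmid, and a bar at the mean of each group. Esrrg-201 reached 141 and 78.6 RPKM with the ERRγ plasmid, and Hspa1b-201 stood at 138 and 156 RPKM in control against 6.62 and 5.96 RPKM with the ERRγ plasmid.

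Inflammatory genes were a further group that was lower with ERRγ. The NF-kB, chemokine and cytokine list had 9 rows of 8 genes, all below both controls in RPKM and negative in each of 5 settings of scaling and test. Their highest median over these settings was −0.71, more than 2 times the 0.26 by which scaling moved the median of all rows. With unique reads under TMM the median was −0.59, less than 2 times the shift there of 0.34. For the list as a whole, scaling thus cannot be told apart from a change. Nos2, the inducible nitric oxide synthase, had 29.8 ± 8.27 RPKM in control and 10.0 ± 1.34 RPKM in ERRγ (SD, n = 2) and fell in the unique-read test (log2 fold change −1.59 ± 0.25, edgeR, adjusted p = 7.14e-06). Cxcl1, a neutrophil chemokine, had 42.0 ± 10.0 and 13.4 ± 0.741 RPKM and fell as well (edgeR, adjusted p = 8.45e-06). Cxcl10-201, for an interferon-induced chemokine, stood at 664 ± 22.8 and 463 ± 19.4 RPKM, and the cytokine gene Lif at 26.3 ± 5.06 and 14.1 ± 0.0314 RPKM. None of the 9 rows passed the all-read test, and 2 passed when adjusted over the list alone. The unique-read test called 7 of 7 rows lower, and 3 of 7 with TMM, and the call of Cxcl10-201 was lost without ERRγ replicate 1 or 2 (edgeR, adjusted p = 0.25 and 0.361). Camera gave an adjusted p of 0.0250, which was 0.611 as the adjusted p with an estimated correlation and 0.0799 without ERRγ replicate 2.

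Immediate early genes, which respond quickly to growth factors and stress, were lower too. All 6 rows of 5 genes lay below both controls in RPKM, with negative log2 fold changes in each of 5 settings of scaling and test. Their highest median over these settings was −0.34, less than 2 times the 0.26 by which scaling moved the median of all rows. Scaling thus cannot be told apart from a change in this list. Egr1-202, for a zinc finger transcription factor, had 73.3 ± 8.63 RPKM in control and 35.5 ± 1.25 RPKM in ERRγ (SD, n = 2), and Egr1-201 had 11.8 ± 1.32 and 5.14 ± 0.60 RPKM. Ier3-201 had 141 ± 4.24 and 91.4 ± 5.32 RPKM, and Junb-201, for an AP-1 subunit, had 273 ± 41.4 and 184 ± 0.530 RPKM. None of the 6 rows passed the all-read test, and 2 passed when adjusted over the list alone. The unique-read test called 5 of 5 rows lower, but only Egr1-201 with TMM. Without ERRγ replicate 1 or 2 the call was lost for Ier3-201 (edgeR, adjusted p = 0.148 and 0.333) and Junb-201 (0.184 and 0.285), and for Egr1-201 without ERRγ replicate 2 (0.216). Camera gave an adjusted p of 0.0501, and 0.0253 with library totals. With an estimated correlation the adjusted p was 0.611 and 0.526.

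Interferon response genes were mostly lower. Of 13 rows of 10 genes, 12 lay below both controls in RPKM and 1 above. Their highest median log2 fold change over 5 settings of scaling and test was −0.22. Scaling moved the median of all rows by up to 0.26, so it cannot be told apart from a change in this list. Ifit2, an interferon-induced antiviral gene, had 21.9 ± 0.213 RPKM in control and 9.94 ± 0.953 RPKM in ERRγ (SD, n = 2) and fell in the unique-read test (log2 fold change −1.13 ± 0.19, edgeR, adjusted p = 1.03e-05). Irf1-202, for a transcription factor of the interferon pathway, had 263 ± 22.4 and 170 ± 7.28 RPKM, and Mx1-205, for an antiviral GTPase, had 54.7 ± 4.79 and 36.6 ± 1.95 RPKM. Rsad2-201, for the antiviral enzyme viperin, had 358 ± 14.9 and 259 ± 17.3 RPKM, but a positive log2 fold change of 0.11 ± 0.32 in unique reads, which were 0.333% of its reads. The abundant rows Mx2-202 (2351 ± 16.3 and 2127 ± 1.43 RPKM) and Gbp2-201 (2271 ± 52.8 and 2020 ± 21.3 RPKM) changed sign between scalings. None of the 13 rows passed the all-read test, and 0 passed when adjusted over the list alone. The unique-read test called 5 of 9 rows lower, and 1 of 9 with TMM, and the call of Mx1-205 was lost without control replicate 1 or ERRγ replicate 1 or 2 (edgeR, adjusted p = 0.336, 0.223 and 0.451). Camera gave an adjusted p of 0.104, and 0.0245 with library totals, which with an estimated correlation became 0.611 and 0.526.

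**Figure D2:**
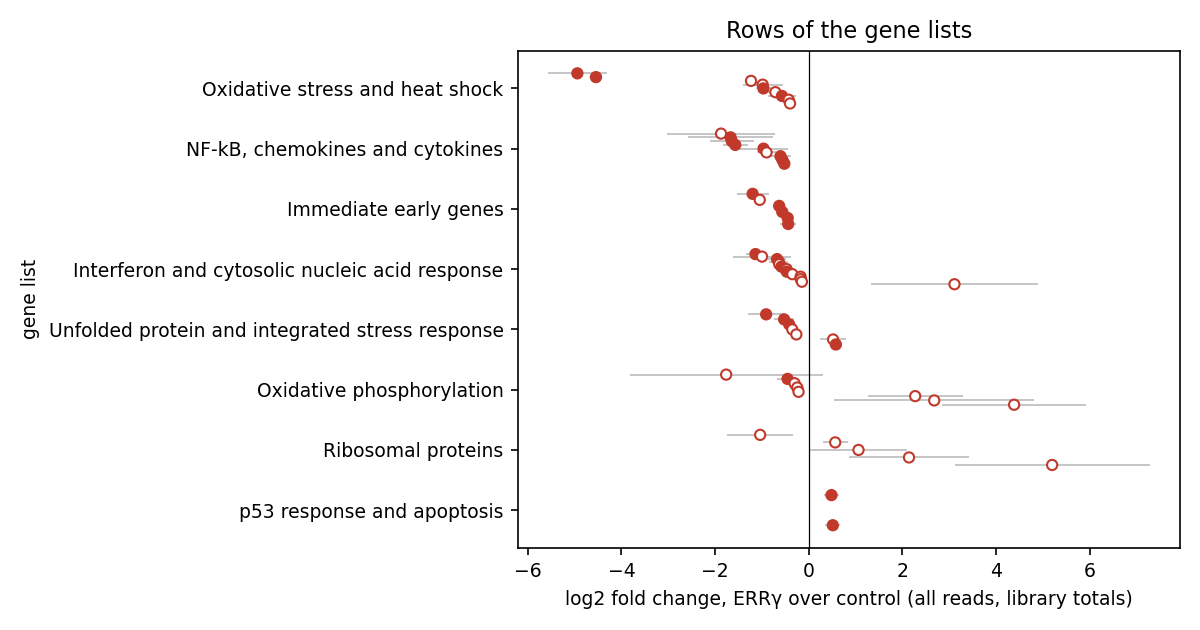
Log2 fold change of each tested row of 8 gene lists, ERRγ over control, from the library-total test, with the SE as a horizontal line; filled points passed the unique-read test. The heat shock rows reach −4.94 for Hspa1a-201, the 2 rows of the p53 list lie above 0, and 3 interferon rows and 2 oxidative phosphorylation rows change sign in other settings of scaling and test.

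Some genes were higher with ERRγ. Txnip, an inhibitor of thioredoxin that is induced by glucose, had 155 ± 10.4 RPKM in control and 232 ± 16.2 RPKM in ERRγ (SD, n = 2). It rose in the unique-read test (log2 fold change 0.58 ± 0.20, edgeR, adjusted p = 0.0203) and missed the threshold of the all-read test (edgeR, adjusted p = 0.0588). Both listed rows of the p53 list rose in the unique-read test, with library totals and with TMM. Cdkn1a, the cell cycle inhibitor p21, had 224 ± 50.4 and 313 ± 2.11 RPKM, and Phlda3, a p53 target that inhibits Akt, had 399 ± 83.8 and 571 ± 36.1 RPKM. In the all-read test neither passed over all rows, and both did when adjusted over the list alone. H1f0, a linker histone on the list for RNA quality, had 226 ± 14.9 and 286 ± 6.87 RPKM and rose in the unique-read test under both scalings. Tinagl1-203 (243 ± 8.44 and 319 ± 12 RPKM) and Maz-201 (67.0 ± 2.94 and 90.5 ± 1.69 RPKM) were among the 5 higher rows with the smallest p in the all-read test, where neither passed, and at most 0.0499% of their reads were unique. The unique-read call was lost without ERRγ replicate 1 or 2 for Txnip (edgeR, adjusted p = 0.198 and 0.332), Phlda3 (0.148 and 0.333), H1f0 (0.290 and 0.409) and Cdkn1a (0.267 and 0.357), for the last also without control replicate 1 (0.101).

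The unfolded protein and integrated stress response list did not move one way. Of its 7 rows, Txnip and Gdf15-202 (65.7 ± 23.1 and 94.3 ± 3.13 RPKM) lay above both controls and 5 lay below. Among the latter were Hspa5-202, for an ER chaperone (447 ± 15.2 and 351 ± 9.71 RPKM), and Asns-201, for asparagine synthetase (87.7 ± 0.472 and 65.7 ± 3.76 RPKM). None of the 7 rows passed the all-read test, and 1, higher, passed when adjusted over the list alone. The unique-read test called 1 row higher and 3 lower of 5, and with TMM 1 higher and 0 lower. Asns-201, 1 of the lower rows, lost its call without control replicate 1 or ERRγ replicate 1 or 2 (edgeR, adjusted p = 0.235, 0.293 and 0.381). Camera gave an adjusted p of 0.831, and 0.863 with an estimated correlation.

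Genes of oxidative phosphorylation, a known target set of ERR receptors, showed no common shift among the few listed. Only 8 of the 80 genes on this list had a listed row, so the target set as a whole was not measured. The 3 rows above both controls were Atp5h-207, Ndufa6-203 and Ndufs6-201, and 3 others lay below. The list pools these with mitochondrially encoded genes. None of its 8 rows passed the all-read test, and 0 passed when adjusted over the list alone. Atp5h-207, for a subunit of ATP synthase, had 0.127 ± 0.179 RPKM in control and 3.06 ± 0.879 RPKM in ERRγ (SD, n = 2), and Ndufa6-203, for a complex I subunit, had 1.12 ± 0.542 and 5.49 ± 0.476 RPKM. Ndufs6-201, a further complex I row, had 1.67 ± 2.36 and 10.7 ± 2.65 RPKM. The mitochondrially encoded mt-Nd4-201 had 66.8 ± 9.45 and 48.8 ± 9.79 RPKM and was the 1 row of 4 that the unique-read test called lower, with 0 called under TMM. Its call was lost without control replicate 1 or ERRγ replicate 1 or 2 (edgeR, adjusted p = 0.156, 0.155 and 0.531). The sign of mt-Co1-201 differed between scalings. Camera pointed upward with an adjusted p of 0.638, or 0.708 with an estimated correlation, while the median log2 fold change of the list was −0.07. Of 5 ribosomal protein rows, Rps3-205 (99.9 ± 1.67 and 148 ± 38.0 RPKM) and Rpl11-210 (1.93 ± 1.51 and 8.56 ± 6.65 RPKM) lay above both controls and Rpl10-201 (19.3 ± 4.46 and 9.40 ± 1.74 RPKM) below. None of the 5 passed the all-read test, and 0 passed when adjusted over the list alone; camera gave an adjusted p of 0.292, and 0.611 with an estimated correlation.

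Other metabolic lists had few rows, and none of those rows passed the all-read test over all rows. For glycolysis, Ldha-202 had 301 ± 16.6 RPKM in control and 347 ± 22.8 RPKM in ERRγ (SD, n = 2), Gpi1-207 had 74.9 ± 20.6 and 107 ± 10.2 RPKM, and Pfkm-201 had 2.92 ± 0.954 and 0.241 ± 0.340 RPKM, and 1 of the 3 passed, higher, when adjusted over the list alone. Rab3a-201, for a secretory vesicle GTPase, stood at 0 RPKM in both controls and at 2.52 and 3.07 RPKM in the ERRγ libraries. Idh3b-204, for a subunit of isocitrate dehydrogenase, stood at 0 RPKM in both controls and at 1.60 and 5.19 RPKM. The transcripts of Hadhb, a gene of fatty acid oxidation, went opposite ways, with Hadhb-202 at 0 RPKM in both controls and at 0.589 and 6.24 RPKM in the ERRγ libraries, and Hadhb-203 at 7.08 ± 1.80 and 1.17 ± 1.18 RPKM. Rab3a-201, Idh3b-204 and 1 Hadhb row passed when adjusted over their list alone. Rab3a-201 and Idh3b-204 were each the only row of their list, and the 2 Hadhb rows the only rows of theirs. With 1 row the adjusted p is the unadjusted p, which was under 0.05 for 141 of all 373 rows tested. Cyp51-204, of sterol synthesis, had 3.48 ± 3.35 and 0.165 ± 0.234 RPKM and did not. The highest share of unique reads among these rows was 7.53%.

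Acta2, Tagln and the matrix gene Thbs1 were lower with ERRγ, while the matrix row Lama5-203 lay above both controls. Acta2 and Tagln, which mark smooth muscle and myofibroblasts, had 170 ± 22.6 and 105 ± 1.74 RPKM, and 699 ± 129 and 528 ± 4.81 RPKM (SD, n = 2). Both fell in the unique-read test with library totals, and neither did with TMM. Without ERRγ replicate 1 or 2 the call was lost for Acta2 (edgeR, adjusted p = 0.148 and 0.206) and Tagln (0.290 and 0.361), for Tagln also without control replicate 2 (0.123). In the all-read test 0 of the 2 rows passed, and 1 passed when adjusted over the list alone. Thbs1 had 224 ± 65.8 and 118 ± 13.1 RPKM and fell in the unique-read test (log2 fold change −0.93 ± 0.15, edgeR, adjusted p = 7.59e-06). Lama5-203, a laminin row, had 4.76 ± 6.73 and 18.3 ± 0.202 RPKM. On the matrix list 0 rows passed the all-read test, and 2 passed when adjusted over the list alone.

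In the remaining lists, Id1-201, for a BMP target, had 261 ± 29.6 RPKM in control and 316 ± 2.61 RPKM in ERRγ (SD, n = 2), passed the all-read test only when adjusted over the list alone, and rose in the unique-read test only with TMM (edgeR, adjusted p = 0.0143). H1f0 passed the all-read test only when adjusted over the list alone. Id1-201 and H1f0 were each the only row of their list, so this adjusted p was the unadjusted p. The antigen presentation list had 4 rows, of which 0 passed over all rows or when adjusted over the list alone; its Psmb8 row had 117 ± 28.5 and 66.0 ± 13.1 RPKM, Tapbp-202 5.65 ± 3.73 and 0.970 ± 1.37 RPKM, Psmb10-202 13.9 ± 8.12 and 3.19 ± 1.33 RPKM, and Psmb10-204 7.98 ± 6.42 and 19.5 ± 3.0 RPKM. Car9-204 of the hypoxia list (2.76 ± 2.64 and 0.0857 ± 0.121 RPKM) and Mapk3-205 of the growth factor signalling list did not pass the filter on low counts and were not tested. Mapk3-205 stood at 14.4 and 0 RPKM in the controls and at 0 RPKM in both ERRγ libraries, so its reads lay in a single library. Actb-201 was the row with the highest mean, at 3396 ± 20.8 and 2760 ± 112 RPKM, and mt-Co1-201 had 1427 ± 255 and 1205 ± 98.2 RPKM; neither passed the all-read, library-total or unique-read test, and the signs of both depended on the scaling or the reads counted.

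Large fold changes were more frequent among rows with few unique reads. Among 279 tested rows with under 10% unique reads, the median absolute log2 fold change with library totals was 2.01, and 70 rows exceeded 4. Among 68 rows with at least 50% unique reads the median was 0.45, and 2 rows exceeded 4, Hspa1a-201 and Gm20481-201. Read number was not matched between these classes. Of the 406 named rows, 22 had 0 reads in both controls and 37 in both ERRγ libraries. Placement and low counts thus cannot be told apart here.

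**Figure D3:**
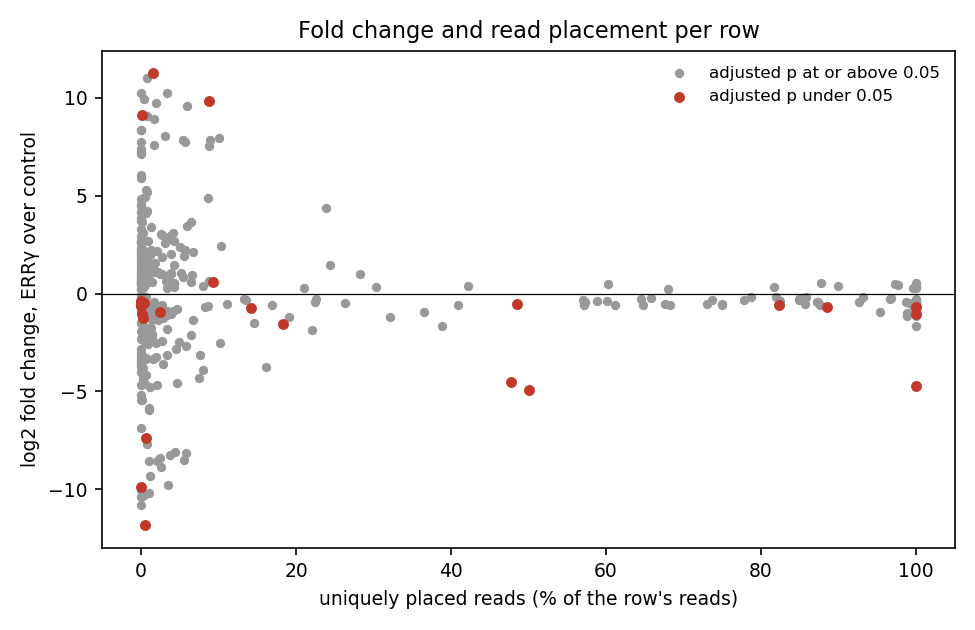
Log2 fold change of each row, ERRγ over control, from the library-total test against the percentage of the row's reads that were uniquely placed; red points have an adjusted p under 0.05. Absolute fold changes on the log2 scale reach 11.84 among rows with under 10% unique reads and 4.94 among rows with at least 50%.

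Libraries of a group were closer to each other than to the other group. Over the 406 rows, which are not independent replicates, Pearson's r of log2(RPKM + 1) was 0.898 between the controls and 0.958 between the ERRγ libraries, against 0.767 to 0.858 between groups. A selection of rows on these samples favours this order. The labels name the libraries of a group as biological replicates, and each was counted as 1 sample. Counts differed by more than sampling noise between the controls (chi-square per degree of freedom 96.5) and between the ERRγ libraries (40.6), which does not show that the samples were independent.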

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

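A signal lay in a row without a gene ID, which no comparison used: it was higher in both ERRγ libraries than in both controls. This row of 894 nucleotides stood at 7.87 and 10.1 RPKM in control replicates 1 and 2 and at 15.8 and 23.2 RPKM in ERRγ replicates 1 and 2, with means of 9.0 ± 1.60 RPKM and 19.5 ± 5.25 RPKM (SD, n = 2). The difference was not tested.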

How the results depend on the processing

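The tests with library totals, unique reads, rows with at least 50% unique reads, added rows of a gene and limma on RPKM were chosen after seeing the data, and the planned change of pseudocount applied to normalised values and was not run for the counts. The list of rows is short and selected, the all-read test recovered few simulated changes, and where a value moved the cause was not tested.

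The all-read test called 1 row (0 higher, 1 lower). It called 7 (2 higher, 5 lower) with DESeq2 size factors, 3 (2 higher, 1 lower) with column totals, 14 (5 higher, 9 lower) with a mean count of at least 50, and 0 to 4 with a library left out (0 to 1 higher, 0 to 3 lower). The DESeq2 Wald test called 200 (111 higher, 89 lower) and limma on log2(RPKM + 1) called 3 (1 higher, 2 lower). Library totals gave 25 (4 higher, 21 lower), rows of a gene added up 36 (6 higher, 30 lower), rows with at least 50% unique reads 51 (6 higher, 45 lower), unique reads with library totals 73 (11 higher, 62 lower), and unique reads with TMM 41 (29 higher, 12 lower). The unique-read count with library totals was 23 (1 higher, 22 lower) without a filter, 18 (3 higher, 15 lower) with an absolute log2 fold change of at least 1, and 10 to 98 with a library left out (1 to 21 higher, 9 to 77 lower). The library-total count was 1 to 2 with a library left out (0 to 1 higher, 1 lower).

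The labels give both groups the replicate numbers 1 and 2. They do not say that the number marks a shared day or batch, so no block was planned. Deviations of same-numbered libraries correlated at −0.0175 over all rows and at 0.223 over rows with at least 50% unique reads. This does not settle whether same-numbered libraries share more than a number. With the replicate number as a block the all-read test called 1 row, the library-total test 1 (0 higher, 1 lower) and the unique-read test 71, the log2 fold change of Esrrg-201 was 10.13 (edgeR, adjusted p = 0.139), and camera gave the immediate early list an adjusted p of 0.0414, which was 0.732 with an estimated correlation.

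The log2 fold change of Esrrg-201 was 9.98 in the all-read test. It passed the threshold at 10.01 with DESeq2 size factors, 10.07 with column totals and 9.95 with a mean count of at least 50. In DESeq2 it passed at 10.08, with library totals at 9.82 and in limma at 6.58. Unique reads under TMM and library totals gave 9.97 and 9.65, and the added rows of the gene 8.90, all past the threshold. Without a filter on low counts it missed the threshold at 9.99 (edgeR, adjusted p = 0.0626). With a library left out it ranged from 9.06 to 16.31. The highest value came without control replicate 1, where the remaining control held no read of this row, so its size is not a measured fold.

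Among the rows named by rule, signs turned for 5. Rsad2-201 was at 0.46 and 0.11 with unique reads under TMM and library totals, and Actb-201 at 0.13 with unique reads under TMM. Mx2-202 was at −0.0069 with a mean count of at least 50, −0.14 with library totals, −0.14 in limma and from −0.0068 to 0.035 with a library left out. Gbp2-201 was at 0.034 with DESeq2 size factors, 0.085 with column totals, 0.034 in DESeq2, 0.17 with unique reads under TMM and from −0.062 to 0.042 with a library left out. mt-Co1-201 was at 0.010 with column totals, 0.052 with unique reads under TMM and from −0.23 to 0.081 with a library left out.

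For the lists, camera's adjusted p is given. With so few libraries camera has little power at an estimated correlation, so a call lost there is no evidence against a shared shift. Nor is a call at the preset of 0.01 secure where the estimate was far higher. For the NF-kB list the estimate was 0.918 in the all-read settings. Oxidative phosphorylation turned with a mean count of at least 50 (0.943), and the unfolded protein response list with column totals (0.940) and with unique reads under TMM (0.900) and library totals (0.799). The interferon list passed with library totals (0.0245) and added rows (0.00828), and ranged from 0.0422 to 0.309 with a library left out. With an estimated correlation these calls were lost (0.526 with library totals, 0.482 with added rows, 0.718 without control replicate 1). The NF-kB list missed the threshold with unique reads and library totals (0.0624), and ranged from 0.000843 to 0.0799 with a library left out. The immediate early list passed without a filter (0.0415), with a mean count of at least 50 (0.0343), library totals (0.0253) and added rows (0.0247), and ranged from 0.00785 to 0.111 with a library left out. With an estimated correlation its adjusted p was 0.503, 0.405, 0.526 and 0.482 in these 4 settings and 0.718 without control replicate 1, and no list passed in any setting (lowest 0.373, the heat shock list with unique reads under TMM). The heat shock list ranged from 0.000487 to 0.0138 with a library left out. Mean correlation within groups exceeded that between groups by 0.116 over all rows and by 0.0560 over rows with at least 50% unique reads.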

Other observations

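The tests in this part were all chosen after the results were seen, and so were the genes named in it. Gm9817, a predicted gene on chromosome 13 (45078692 to 45081222, GRCm38), had 135 ± 27.5 RPKM in control and 64.7 ± 5.70 RPKM in ERRγ (SD, n = 2). It fell in the unique-read test (log2 fold change −1.07 ± 0.16, edgeR, adjusted p = 4.01e-06) and kept its call with any library left out. Csf2, for the cytokine GM-CSF, had 10.8 ± 2.68 and 3.38 ± 0.121 RPKM and kept its call in the same way. Tslp, for a further cytokine, had 11.6 ± 2.85 and 5.23 ± 1.03 RPKM and fell in the unique-read test under both scalings, but not without ERRγ replicate 2 (edgeR, adjusted p = 0.206). Cryab, for a small heat shock protein, went against the heat shock list. Its row Cryab-201 had 25.7 ± 6.18 and 40.1 ± 2.82 RPKM and rose in the unique-read test (log2 fold change 1.01 ± 0.41, edgeR, adjusted p = 0.0374), with 3.64% unique reads, and the call was lost without control replicate 2, ERRγ replicate 1 or ERRγ replicate 2 (edgeR, adjusted p = 0.251, 0.339 and 0.358).

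Vcl, Actn1, Tpm4 and Msn were lower in both ERRγ libraries. Vcl-201, for the adhesion protein vinculin, had 97.1 ± 18.2 RPKM in control and 67.3 ± 4.14 RPKM in ERRγ (SD, n = 2), and Actn1-201, for an actin crosslinker, had 180 ± 20.4 and 121 ± 6.06 RPKM. Tpm4-201, for a tropomyosin, had 486 ± 17.3 and 393 ± 21.0 RPKM, and Msn-201, for the membrane linker moesin, had 141 ± 28.0 and 105 ± 5.14 RPKM. These 4 rows passed the unique-read test (edgeR) with library totals. None of the 4 passed with TMM, and none without ERRγ replicate 1 (adjusted p from 0.184 to 0.252) or ERRγ replicate 2 (0.361 to 0.485). Msn-201 also missed the threshold without control replicate 1 (edgeR, adjusted p = 0.0543).

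The lower heat shock rows were weighed against 2 technical explanations. Reads moved between Hspa1a and Hspa1b would leave their sum in place, but the reads of both rows and of Gm20481 added together were lower by a log2 ratio of −4.59, from 8573 and 8876 reads in the controls to 366 and 326 in the ERRγ libraries. Scaling moved the median of all rows by 0.26 at most with all reads, and log2 fold changes by a median of 0.34 with unique reads, while the highest median log2 fold change over 7 settings was −4.39 for the Hspa1a and Hspa1b rows. For the other rows of the list the highest median was −0.46, less than 2 times the shift, so scaling cannot be told apart from a change in these rows. Handling of the cells and uptake of the plasmids were not varied separately from ERRγ. The control plasmid carries EGFP, and neither untransfected cells nor an empty plasmid were included. Lower with ERRγ thus cannot be told apart from higher with EGFP, and the cause of the difference was not tested.

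In 13 of 25 genes with several tested rows, rows of the gene had opposite signs. The median of their larger absolute log2 fold change was 2.84 and that of the added reads 0.38, and no row of these genes had over 8.20% unique reads. If shared reads were placed differently in each library, the controls would differ more on these rows than on well-placed rows of like read number: the ratio of the median differences was 1.60 (95% bootstrap interval 0.939 to 2.64), and over all rows with few unique reads it was 1.27 or 0.783 depending on how rows were matched. A switch between transcripts needs well-placed rows to be seen, and 0 of the 13 genes had at least 2 rows with at least 50% unique reads. Read placement and a switch cannot be told apart with so few unique reads.

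Pseudogene rows followed the protein-coding gene they resemble. Of 29 pseudogene rows, 19 had their closest protein-coding gene among the listed rows (7 genes, among them Actg1, Hspa8, Hsp90aa1 and Hsp90ab1), all 19 had a negative log2 fold change with library totals, and 15 passed the unique-read test. That test called 73 of 121 rows, and the median log2 fold change of all its rows was −0.38. With TMM it called only 12 rows lower. These included the falling rows of the core, an Egr1 row and Tslp, so most of the 15 pseudogene calls were lost with TMM. Actg-ps1 on chromosome 8 (46228994 to 46230117, GRCm38) stood at 1187 ± 92.4 RPKM in control and 805 ± 18.6 RPKM in ERRγ (SD, n = 2), beside 1290 ± 110 and 846 ± 74.6 RPKM for Actg1-204, although 82.3% of its reads were counted as unique, and its call was lost without ERRγ replicate 1 or 2 (edgeR, adjusted p = 0.148 and 0.242). The median absolute difference in log2 fold change between a pseudogene and its gene was 0.074, against 0.17 with shuffled genes (permutation test, one-sided p = 0.0031, 10000 shuffles). The shuffles treated the 19 rows as independent although they share 7 genes, so this p overstates the evidence. Reads of the parent gene placed on the copy could give such a match. However, 16 of the 19 rows had at least 50% unique reads, and identity to the gene ranged from 79.6% to 99.7%. Whether reads were misplaced was thus not settled. Variants of the NOD strain that could make such reads look unique, and transcription of the copies themselves, were not tested.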
